A study of Mus musculus with 72 samples.

How the data were processed

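The labels name total RNA from interfollicular epidermis, the sheet of skin epithelium between the hair follicles, and the selection of RNA for the libraries is not given in the sources used here. Per the labels' protocols, back skin was scraped free of fat, the epidermis was lifted off the dermis with the enzyme dispase, and the dissociated, filtered cells were frozen before RNA extraction. Each of the 72 libraries came from 1 female mouse of 8 weeks, and 4 mice were taken per genotype at each of 6 time points. Genotype, time point and replicate number were read from the labels. The labels give a span of 156 to 176 h of darkness and no hour for each time point, so even steps of 4 h in label order were assumed. All peak times are therefore hours after time point 1 and do not refer to the former light schedule.

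The deposited files hold raw read counts per Ensembl mouse gene, 1 file per library. Per the submitters' processing notes, the authors used Trimmomatic, TopHat2 2.1.1 and featureCounts with the mouse build GRCm38 (mm10). The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Counts of overlapping genes on opposite strands, of pseudogenes and of near-identical paralogs are uncertain for that reason. Symbols, gene types and coordinates were taken from the GENCODE mouse annotation of GRCm38, which matched 45229 of the 46078 gene identifiers and left 849 without a symbol. No count at all was recorded for 13937 genes.

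Everything that follows was computed from those counts. Total counts per library ran from 24.5 to 95 M with a median of 35.4 M. At this depth the spread between animals was far larger than counting error: in all 108 pairs of replicates the counts differed by more than sampling noise, with a chi-square per gene of 8.36 to 293, so that no library was treated as a duplicate of another. Genes were kept by edgeR's filterByExpr with the 18 combinations of genotype and time point as groups and a minimum count of 10, which left 18538 genes. TMM factors ran from 0.866 to 1.11. The common dispersion was 0.0584.

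The main test was edgeR's quasi-likelihood F test with robust estimation (edgeR 4.0.16 in R 4.3.3) on 1 model of all 72 libraries, in which each genotype had its own mean, cosine and sine term of a 24 h cycle. This left 63 residual degrees of freedom. A 24 h rhythm in a genotype was a joint test of its cosine and sine terms; a different rhythm between genotypes was a joint test of the differences of those terms; a different mean level was a test of the difference of the means over the cycle. P-values were adjusted by the Benjamini-Hochberg method over the 18538 genes, and an adjusted p under 0.05 was called. Rhythm sizes are peak-to-trough differences of the fitted cosine on the log2 scale with their standard errors. Those standard errors came from the model's log2 coefficients, and a check against edgeR's own statistics found 99.1% of genes within 10%. Levels are CPM (counts relative to the TMM-scaled library total), and log2 CPM used a prior count of 2.

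Gene lists for clock outputs, epidermal layers, cell cycle, metabolism, stress and other skin cell types, 31 in all, were fixed together with the tests and the rule for named genes before the data were examined. Their mean levels were compared with all other genes by camera with a preset correlation of 0.01 and again with an estimated correlation (limma 3.58.1), and tested on their own by fry. Their share of rhythmic genes was compared with that of all other genes by a one-sided Fisher's exact test. That test counts genes as independent, so its p-values overstate the evidence where the members of a list are correlated. Adjustment was over the lists within a genotype or comparison. Counts adjusted over the list alone are given beside counts adjusted over all genes. Lists overlap: the clock outputs driven through E-boxes and the clock genes with ROR elements are mostly members of the core clock list.

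Named genes were, by rule, the members of the core clock list in every comparison, the 10 largest rhythms of each genotype, the 8 genes outside the core clock list with the smallest p for each difference of rhythm, the 8 most increased and 8 most decreased genes of each difference of mean level with the same sign at all 6 time points, and up to 4 members of each list with the smallest adjusted p. The ranked parts of the rule required a called gene with a mean log2 CPM of at least 1. Any other gene is said in the text to have been chosen after its values were seen. Some genes that these rules name were counted in the totals but are not reported here.

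The procedures were tested on simulated counts for the same 18538 genes, drawn from their overall means, dispersions and library sizes, with 200 genes given a rhythm in WT and 200 others a change of level in KO. For rhythms in WT, 58.2%, 86.6% and 98.5% of genes with a peak-to-trough fold of 1.5, 2 and 4 were called, with 6 of 18338 unchanged genes called, and 94.5% of fitted peaks lay within 2 h of the true one. For different rhythms of KO and WT the shares were 38.8%, 68.7% and 90.9%, with 10 unchanged genes called. For different mean levels of KO and WT they were 77.6%, 97.0% and 100%, with 5 unchanged genes called. A rank test of rhythms in WT called 34.3%, 67.2% and 86.4%, with 2 unchanged genes. Of 30 unchanged lists, camera called 0 and fry called 1. Each gene was drawn independently and the lists were filled at random, so the simulated genes were not correlated. These false calls therefore do not show how often correlated genes or lists are called falsely.

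Alternatives fixed in advance were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma voom with sample weights, only the genotypes concerned, each replicate number left out in turn, the replicate number as a block, time point as a factor with 6 levels, a rank test against cosine templates and a minimum fold of 1.5. Added after the data were seen were each single library left out in turn, the library of each genotype lowest on the first principal component left out, each time point left out in turn, and 24 h terms tested as contrasts of the time point means. For each count of called genes, 75 assignments of libraries to time points or genotypes, the real one included, were compared. Coordinates, where printed, count from 1.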

Results

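Interfollicular epidermis was compared between mice with the clock gene Arntl (Bmal1) intact (WT), mice in which a stop cassette blocks it (KO) and mice in which keratinocyte Cre removes the cassette (RE), all after 6 to 7 days of darkness. Each genotype was represented by 24 libraries, 4 animals at each of 6 time points. Total counts ran from 27.6 to 46.4 M in WT, 24.5 to 44.9 M in KO and 25.6 to 95 M in RE, where replicate 2 of time point 6 was the largest. Mitochondrial reads made up 2.93 ± 1.34% in WT, 2.71 ± 0.683% in KO and 2.61 ± 0.740% in RE (mean ± SD). The first 2 principal components of log2 CPM held 13.5% and 9.5% of the variance, and the library lowest on the first one lay at time point 6 in each genotype (replicate 4 in WT and KO, replicate 1 in RE).

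Arntl itself lies on chromosome 7 at 113207465-113314126 of the plus strand (GRCm38). In WT it cycled from 96.1 ± 3.28 CPM at time point 1 through 44.5 ± 8.48, 22.8 ± 3.76, 25.5 ± 6.74 and 52.0 ± 18.5 to 83.6 ± 21.4 at time point 6 (mean ± SD, n = 4). KO animals held 31 ± 1.30, 31.4 ± 1.60, 31.3 ± 0.603, 31.6 ± 2.46, 31.2 ± 2.75 and 29.0 ± 2.01 CPM at the same time points. RE animals held 64.1 ± 8.84, 62.8 ± 11, 63.3 ± 5.40, 53.5 ± 1.52, 57.9 ± 9.01 and 64.3 ± 7.97 CPM. Single animals spanned 18.1 to 99.2 CPM in WT, 26.1 to 35.1 in KO and 47.1 to 76.2 in RE, so every KO animal lay below every RE animal. At time point 6 replicate 4 of WT had 52.4 CPM and the other 3 WT animals 87.4 to 99.2.

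The clock of WT epidermis ran with large amplitude after a week without light. The repressor Per2 swung by 4.51 ± 0.40 log2 units between peak and trough (standard error, n = 24 animals, adjusted p = 8.28e-11), from 4.12 ± 1.76 CPM at time point 1 to 147 ± 16.2 at time point 4. The output factor Dbp swung by 4.67 ± 0.42, from 2.59 ± 0.619 to 127 ± 19.1 CPM at time point 3. With hours counted from time point 1, genes with ROR elements peaked last. Arntl peaked at 21.8 h (2.19 ± 0.13, adjusted p = 2.05e-20) and its partner Clock at 21.5 h (0.50 ± 0.08). The Clock paralog Npas2 peaked at 22.1 h (2.82 ± 0.27) and the repressor Cry1 at 16.5 h (1.99 ± 0.20). Genes with E-boxes peaked in the opposite part of the cycle. Among them were the nuclear receptors Nr1d1 (3.45 ± 0.35, 7.09 h) and Nr1d2 (2.29 ± 0.21, 9.22 h), Per1 (1.77 ± 0.34, 10.3 h), Per3 (2.90 ± 0.27, 11.1 h) and Cry2 (1.39 ± 0.14, 10.4 h). The PAR factors Tef (2.68 ± 0.21, 10.6 h) and Hlf (0.84 ± 0.17, 10.6 h) and the repressors Bhlhe41 (2.56 ± 0.30, 9.62 h) and Ciart (3.95 ± 0.29, 9.83 h, adjusted p = 9.6e-16) shared that phase. Of the 19 core clock genes 16 were rhythmic, the same 16 when adjusted over the list alone, and Rora (adjusted p = 0.248), Nfil3 (0.449) and Bhlhe40 (0.249) were not. In the lists, 13 of 15 E-box outputs and 4 of 5 ROR element genes were rhythmic, more than among other genes (Fisher's exact test, adjusted p = 2.96e-12 for the core clock, 2.08e-10 and 0.00339).

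**Figure D1:**
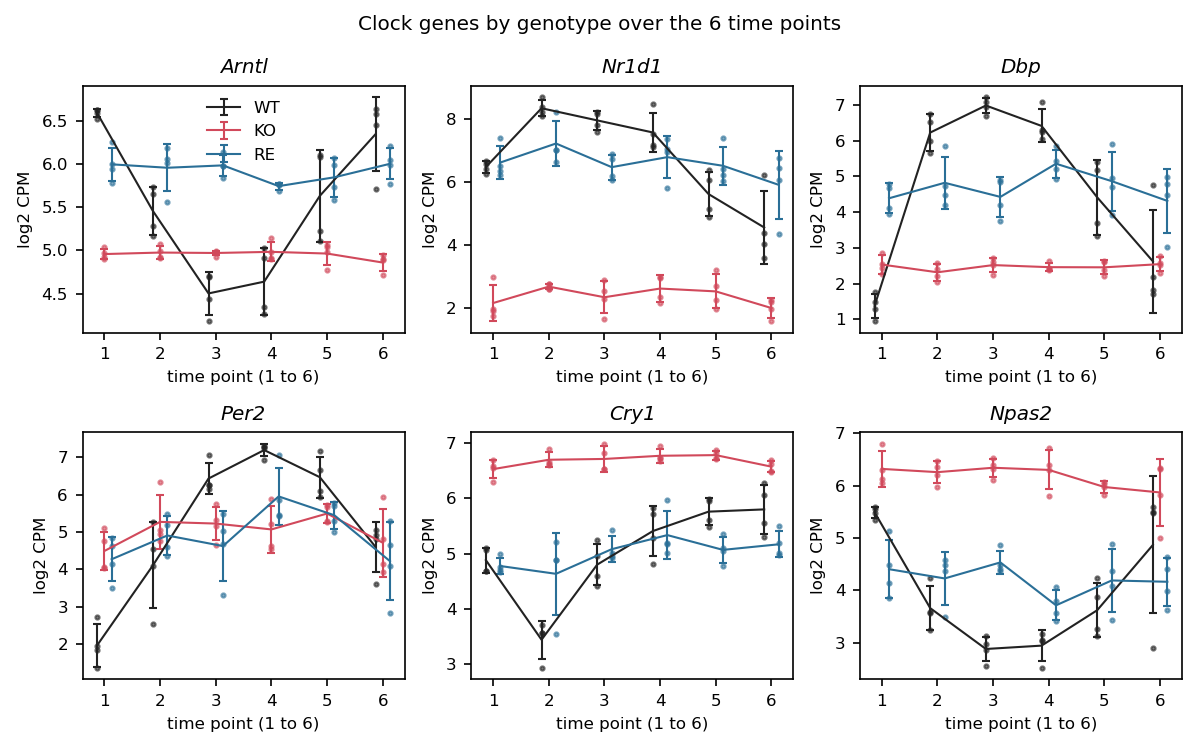
Expression of 6 clock genes (log2 CPM) at the 6 time points in WT (black), KO (red) and RE (blue); points are animals, lines join means and bars are SD of 4 animals. Nr1d1 averaged 161 CPM in WT, 5.49 in KO and 109 in RE.

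The cell cycle was rhythmic in WT, with DNA synthesis and division in opposite parts of the day. S phase genes peaked near 12 h. Among them were the transcription factor E2f1 (1.92 ± 0.29 log2 peak to trough, 11.5 h), the helicase subunit Mcm6 (1.26 ± 0.20, 11.2 h) and the chromatin assembly factor Chaf1b (1.48 ± 0.23, 11.9 h). G2 and mitosis genes peaked near 23 h. Among them were the centromere proteins Cenpa (1.68 ± 0.24, 23.5 h) and Cenpf (1.93 ± 0.32, 23.4 h), the cyclin Ccnb2 (1.73 ± 0.28, 22.8 h) and the phosphatase Cdc25c (1.91 ± 0.32, 23.1 h). Of 32 mitosis genes 30 were rhythmic (32 when adjusted over the list alone, Fisher's exact test, adjusted p = 1.57e-25), and of 30 S phase genes 25 (28; 1.09e-18). The estimated correlation between members was 0.868 for mitosis and 0.774 for S phase. Fisher's test counts genes as independent, so these p-values overstate the evidence. DNA repair genes were rhythmic in 8 of 26 cases (12; 0.0211). Their peaks included those of Lig1 (1.15 ± 0.23, 12.2 h), Apex1 (0.46 ± 0.09, 9.56 h), Msh6 (0.45 ± 0.10, 12.0 h) and Fanca (1.10 ± 0.25, 15.2 h). Without replicate 3 of WT at time point 2 the list had 5.

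Glucocorticoid targets were rhythmic in 7 of 15 cases in WT (9 when adjusted over the list alone, Fisher's exact test, adjusted p = 0.00337). The leucine zipper protein Tsc22d3 (1.84 ± 0.31, 10.6 h), the chaperone Fkbp5 (2.38 ± 0.50, 11 h) and the mTOR inhibitor Ddit4 (0.95 ± 0.17, 6.58 h) led them. Glycolysis had 7 of 21 (9; 0.0211). Its members were led by the regulators Pdk1 (0.44 ± 0.09, 8.42 h) and Pfkfb3 (1.01 ± 0.24, 8.73 h). Pfkm (0.29 ± 0.08) had adjusted p = 0.0688 without replicate 1 of WT at time point 5. Gpi1 (0.34 ± 0.09) had 0.0908 without replicate 2 of WT at time point 3, which left 3 glycolysis genes. Other lists were not enriched. Heat shock had 5 of 17 (6; 0.109) and 3 without replicate 1 of WT at time point 2, with the chaperones Hsp90b1 (0.75 ± 0.12, 20.5 h) and Hsph1 (0.94 ± 0.18, 18.7 h) and the cold-induced Cirbp (0.78 ± 0.20, 5.54 h). Antioxidant response had 4 of 22 (4; 0.608), with Sod2 (0.72 ± 0.09, 12.7 h), Prdx6 (0.49 ± 0.09) and Nqo1 (0.82 ± 0.16, 1.26 h). NAD metabolism had 3 of 11 (3; 0.344), with Nmnat2 (1.42 ± 0.28, 5.77 h), Nadk (0.31 ± 0.08) and Nampt (0.37 ± 0.10, adjusted p = 0.119 without replicate 4 of WT at time point 4). Fatty acid oxidation had Ucp2 (0.82 ± 0.12) and Acadl (0.52 ± 0.09, 23.8 h), and the basal layer had the hemidesmosome protein Dst (1.46 ± 0.22, 9.09 h) and Lama3 (0.55 ± 0.16; 0.0747 without replicate 4 of WT at time point 2). Differentiation had Tgm3 (1.62 ± 0.34, 10.9 h), Aloxe3 (0.79 ± 0.20; 0.0568 without replicate 2 of WT at time point 1) and Krt2 (1.69 ± 0.44; 0.940 without replicate 4 of WT at time point 6).

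Single members were rhythmic in WT for inflammation (the alarmin Il33, 1.15 ± 0.24, 23.9 h), lipid synthesis (Acaca, 0.44 ± 0.10), cholesterol synthesis (Sc5d, 0.53 ± 0.16), melanocyte (Mitf, 0.46 ± 0.12), adipocyte (Pnpla2, 0.36 ± 0.10) and muscle markers (Acta1, 2.64 ± 0.85). Sc5d had adjusted p = 0.111 without replicate 4 of WT at time point 4, Mitf 0.0617 without replicate 3 of time point 6, Pnpla2 0.0784 without replicate 2 of time point 1 and Acta1 0.225 without replicate 4 of time point 6. The inflammation list had 5 calls without replicate 1 of RE at time point 5. The other 11 lists held 173 genes, 0 of them rhythmic in edgeR (13 at an unadjusted p under 0.05, DESeq2 called 1 and voom 6). They were oxidative phosphorylation, immediate early, interferon, Langerhans cell, dendritic epidermal T cell, fibroblast, endothelium, hair follicle, sebaceous gland, erythrocyte and Merkel cell. Among the largest rhythms outside the clock were the gut peptide Pyy (3.71 ± 0.58, 12.6 h), the mitochondrial folate enzyme Mthfd1l (2.78 ± 0.25, 12.1 h), and the pseudogene Gm9989 (2.97 ± 0.32). The microRNA gene Gm23935 (2.90 ± 0.58) had adjusted p = 0.274 without replicate 4 of WT at time point 1. In all, 2031 of 18538 genes were rhythmic in WT (4683 at an unadjusted p under 0.05), with a median swing of 0.50 log2 units and 422 genes at 2-fold or more. Peaks gathered at time points 3 and 4 (459 and 469 genes), and 4.9% of the genes were pseudogenes against 8.6% of those tested. The count was 1019, 1246, 1330, 1224 and 3261 without time points 1, 2, 3, 5 and 6.

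**Figure D2:**
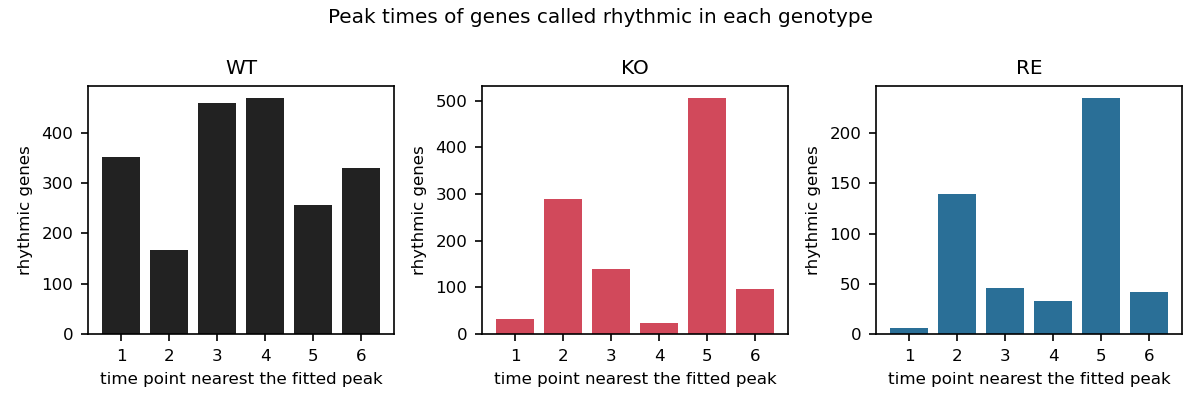
Number of rhythmic genes by the time point nearest to their fitted peak in WT, KO and RE. WT peaks spread over the cycle with 459 genes at time point 3, while 506 of the KO genes peaked at time point 5.

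Clock gene rhythms were not detected in KO epidermis. In KO Dbp stayed between 4.97 and 5.81 CPM and Nr1d1 between 4.05 and 6.42 CPM (means of 4 animals), and 0 of 19 core clock genes were rhythmic in edgeR (2 at an unadjusted p under 0.05, DESeq2 called 0 and voom 2). The difference of rhythm from WT was called for 15 of the 19 (17 when adjusted over the list alone), with the smallest adjusted p for Arntl (9.46e-14) and Tef (1.80e-08). Per1, Rora, Nfil3 and Bhlhe40 were not called. Hlf (0.0339) was lost when any of 16 libraries was left out, with 0.0738 without replicate 1 of KO at time point 6. Outside the clock the smallest p was that of Ttc9, a tetratricopeptide protein (2.12 ± 0.14 at 22.1 h in WT, adjusted p of the difference = 5.24e-10). Next came the elongation factor Leo1 (0.98 ± 0.09, 21.2 h), the vitamin B6 kinase Pdxk (1.35 ± 0.12, 13.4 h), the chemokine Cx3cl1 (0.94 ± 0.09, 12.1 h) and Fam234b (0.96 ± 0.09, 21.7 h). The repressor Zhx2 moved its peak from 13.9 h in WT (0.57 ± 0.06) to 3.91 h in KO (0.30 ± 0.07). The ribosomal pseudogene Rps15a-ps4 and the retrogene Rps27rt swung by 0.97 ± 0.10 and 1.23 ± 0.12 in KO with peaks near 16 h, and reads of their parent genes make both uncertain. In all, 1150 genes had a different rhythm in KO and WT (4124 at an unadjusted p under 0.05), with the larger swing in WT for 708 and in KO for 442. The count was 352, 171, 461 and 934 without replicate numbers 1, 2, 3 and 4, 574 with time point as a factor, 1582 with DESeq2 and 3193 with voom.

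Among the lists, mitosis had a different rhythm in 31 of 32 genes between KO and WT (31 when adjusted over the list alone). S phase had 12 of 30 (23), and 4 without replicate 2 of KO at time point 4. E-box outputs had 11 of 15 (14), ROR element genes 4 of 5 (5) and DNA repair 4 of 26 (8), with 1 without replicate 2 of WT at time point 5. Antioxidant response, fatty acid oxidation, glucocorticoid targets and heat shock had 2 each, glycolysis, NAD metabolism, the basal layer and inflammation 1 each. In the other 17 lists, 0 of 270 genes were called in edgeR (27 at an unadjusted p under 0.05, DESeq2 called 1 and voom 16). In KO alone the mitotic kinases Plk1 (1.11 ± 0.30, 8.75 h) and Aurka (0.79 ± 0.22, 8.07 h) and the kinesin Kif20a (0.98 ± 0.27, 8.13 h) peaked far from their WT times. These 3 of 32 mitosis genes (27 when adjusted over the list alone) numbered 0 without replicate 1 of KO at time point 1 and 8 without its replicate 3 at time point 6. Leaving out replicate 4 of KO at time point 3 gave adjusted p = 0.136 for Plk1 and 0.172 for Aurka, and leaving out replicate 4 at time point 6 gave 0.117 for Kif20a.

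In KO 1088 genes were called rhythmic (4306 at an unadjusted p under 0.05), with a median swing of 0.42 and 155 at 2-fold or more. Of these calls 506 peaked at time point 5 and 289 at time point 2, and 9.4% were pseudogenes. The stem cell marker Cd34 had the largest swing (3.94 ± 0.83, 22.9 h, adjusted p = 0.00997), and Gm10382 swung by 1.60 ± 0.29 (15.7 h). The other 8 of the 10 largest were lost without replicate 4 of KO at time point 6: Adcy1 (adjusted p = 0.208), the globin Hbb-bs (0.542), Col8a2 (0.0949), Il31ra (0.0841), Igdcc4 (0.0554), Sncg (0.172), Tspan2 (0.369) and the follicle factor Lhx2 (0.235). Hair follicle genes with a call were Cd34, Lhx2 and Trps1 (3 of 22), with 1 left without replicate 1 of WT at time point 2. Further calls were Ercc2 and Parp1 in DNA repair, Nadsyn1 and Parp1 in NAD metabolism, and E2f8, Cox5a, Smpd1, Nr3c1, Bag3, Col6a1, Mylpf and Hbb-bs in 1 list each. No list was enriched (Fisher's exact test, adjusted p = 1 for each). Ercc2 (adjusted p = 0.0502), Cox5a (0.104), Smpd1 (0.0747), Nr3c1 (0.0669) and Col6a1 (0.140) were lost without replicate 2 of KO at time point 5. Bag3 (0.129) was lost without replicate 4 of time point 3, Trps1 (0.167) without replicate 4 of time point 2, E2f8 (0.0834) without replicate 1 and Mylpf (0.0643) without replicate 4 of time point 6. In 19 lists 0 of 282 genes were called in edgeR (43 at an unadjusted p under 0.05, DESeq2 called 5 and voom 16). The count was 202, 1924, 554 and 681 without time points 2, 3, 5 and 6, 645 without replicate 2 of KO at time point 5, and 17 by the rank test. Of the KO genes 106 were also rhythmic in WT (119 expected), 50 of them (47.2%) with peaks within 4 h, where random peaks give 33.3%.

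With Arntl in keratinocytes alone, rhythms shared by the animals were nearly absent from the clock genes. Per2 was the 1 rhythmic gene among 19 (1.51 ± 0.40, 12.1 h, adjusted p = 0.0449), with 6 genes at an unadjusted p under 0.05, 1 called by DESeq2 and 3 by voom. Its call was lost when any of 21 libraries was left out, with 0.263 without replicate 3 of RE at time point 4. Dbp lay between 21.5 and 41.9 CPM and Nr1d1 between 71.6 and 166 CPM in RE (means of 4 animals). A rhythm different from WT was called for 14 of the 19 genes (15 when adjusted over the list alone), led by Arntl (adjusted p = 6.84e-12) and Ciart (1.52e-06). Outside the clock Ttc9 (9.26e-10), Leo1, Fam234b and the phosphatase Inpp1 (0.92 ± 0.13 at 7.25 h in WT) differed most, beside the ribosomal and other pseudogenes Rps15a-ps4, Rpl31-ps14 and Gm11663 and the retrogene Rps27rt (1.16 ± 0.12 in RE), which are uncertain. In all, 402 genes differed (2689 at an unadjusted p under 0.05), with the larger swing in WT for 240 and in RE for 162. The count was 58, 98, 65 and 276 without replicate numbers 1, 2, 3 and 4, 192 with time point as a factor, 696 with DESeq2 and 2645 with voom.

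No rhythm of mitosis genes was detected in RE, where their median swing was 0.15 log2 units. Of 32 genes 0 were rhythmic in edgeR (0 at an unadjusted p under 0.05, DESeq2 and voom called 0), and 9 differed in rhythm from WT (30 when adjusted over the list alone). This number was 3 without replicate 2 of WT at time point 1 and 15 without replicate 2 of RE at time point 6. Of 30 S phase genes 0 were rhythmic in RE (1 at an unadjusted p under 0.05, DESeq2 and voom called 0) and 2 differed from WT (16). Without replicate 2 of WT at time point 1 the number was 0, and without replicate 2 of RE at time point 1 it was 7. E-box outputs differed from WT in 10 of 15 cases (11), ROR element genes in 4 of 5 (4), heat shock in 2 of 17 (4) and hair follicle in 2 of 22 (7). DNA repair, antioxidant response, lipid synthesis, fatty acid oxidation and glucocorticoid targets had 1 each. The other 19 lists had 0 of 298 genes in edgeR (27 at an unadjusted p under 0.05, DESeq2 called 2 and voom 26). Between RE and KO edgeR called 0 genes for a different rhythm (364 at an unadjusted p under 0.05, DESeq2 and voom called 0), in the lists 0 of 515 (16 at an unadjusted p under 0.05).

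In RE 501 genes were called rhythmic (3006 at an unadjusted p under 0.05), with a median swing of 0.41 and 86 at 2-fold or more. Of these calls 235 peaked at time point 5, and 15.4% were pseudogenes. The transcription factor Scand1 (2.36 ± 0.30, 14.9 h, adjusted p = 3.87e-06), the neurotrophic factor Nrtn (1.70 ± 0.31, 14.7 h) and the pseudogene Gm5814 (1.54 ± 0.24, 14.9 h) kept their calls whichever library was left out. Inflammation and barrier stress had 7 of 24 (12 when adjusted over the list alone, Fisher's exact test, adjusted p = 7.27e-05) and 0 without replicate 1 of RE at time point 5. Without that animal adjusted p was 0.0745 for the alarmin S100a8 (6.70 ± 1.05), 0.131 for S100a9 (6.70 ± 1.10), 0.566 for Lcn2 (4.58 ± 0.94) and 0.891 for Slpi (3.87 ± 0.97). For other genes it was 0.506 for Ccl20 (3.51 ± 0.76), 0.173 for Sprr2d (6.60 ± 1.37), 0.466 for Slc7a11 (3.51 ± 0.72) and 0.143 for Gsta4 (2.21 ± 0.41). It was 0.874 for BC100530 (3.42 ± 0.83), 0.982 for Stfa1 (2.47 ± 0.68), 0.863 for the pseudogene Gm11597 (2.34 ± 0.62) and 0.890 for Pla2g4e (1.64 ± 0.46). Pi15 (2.30 ± 0.58) had 0.769 without replicate 1 of RE at time point 6, Zbtb16 (1.93 ± 0.44) 0.112 without replicate 4 at time point 3, and Acaca (0.37 ± 0.10) 0.130 without replicate 1 at time point 2. Smpd1 (0.44 ± 0.10) and Jund (1.10 ± 0.22) completed the calls in lists. In 23 lists edgeR called 0 of 368 genes (36 at an unadjusted p under 0.05, DESeq2 called 4 and voom 24). The count was 179 and 246 without time points 2 and 5, 302 without replicate 4 of time point 5, 880 without replicate 2 of time point 6, and 0 by the rank test. Of the RE genes 305 were also called in KO (29.4 expected), all with peaks within 4 h, and 54 in WT (54.9 expected), 37 of these (68.5%) within 4 h, where random peaks give 33.3%.

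**Figure D3:**
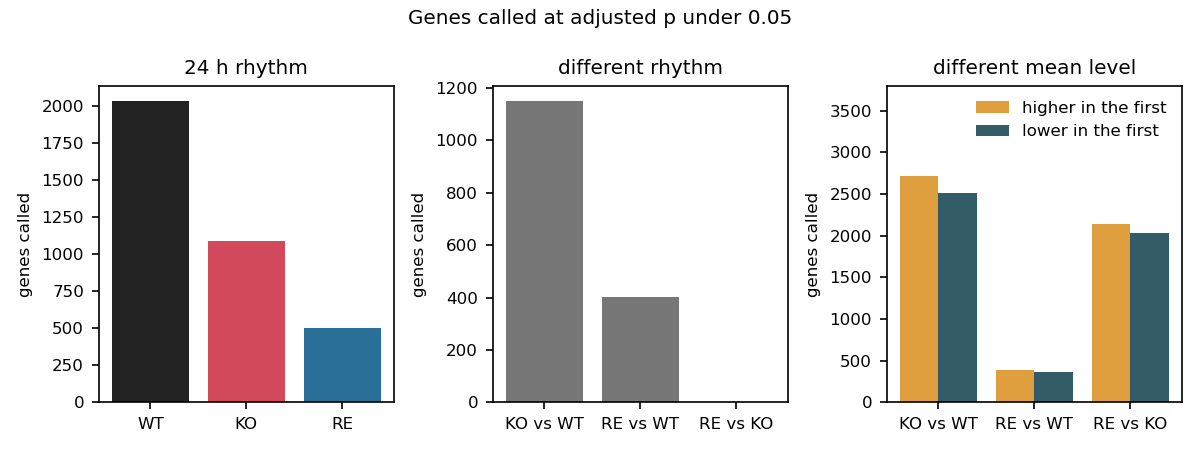
Genes called for a 24 h rhythm in each genotype, for a different rhythm and for a different mean level between genotypes, with genes higher and lower shown apart. Rhythms numbered 2031 in WT, 1088 in KO and 501 in RE.

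In KO the E-box outputs of the clock fell and its ROR element genes rose (against WT, 24 animals each). Nr1d1 fell by 4.46 ± 0.18 log2 units, Nr1d2 by 2.92 ± 0.11, Dbp by 2.58 ± 0.22, Per3 by 2.22 ± 0.14, Ciart by 1.80 ± 0.15 and Bhlhe41 by 1.33 ± 0.15. Tef fell by 0.86 ± 0.10, Arntl by 0.61 ± 0.07, Bhlhe40 by 0.60 ± 0.19 and Hlf by 0.34 ± 0.08. Genes held down by Nr1d1 and Nr1d2 rose: Npas2 by 2.21 ± 0.13, Cry1 by 1.60 ± 0.10, Nfil3 by 0.71 ± 0.18 and Clock by 0.33 ± 0.04. Among genes outside the clock with the same sign at all 6 time points, tissue factor F3 (2.09 ± 0.19), the imprinted RNA H19 (2.01 ± 0.23) and the lipase Abhd12b (1.93 ± 0.10) were among those that rose most. The transporter Slc46a2 (1.86 ± 0.16), the fetal RNA binder Igf2bp2 (1.74 ± 0.14) and the Fc receptor Fcgr3 (1.70 ± 0.14) came next. The growth factor binder Igfbp5 (-3.06 ± 0.22), the sulfatase Arsi (-2.28 ± 0.16), the pore former Gsdmc (-2.22 ± 0.27) and the pseudogenes Ifi203-ps (-3.24 ± 0.18) and Gm9989 (-2.68 ± 0.18) fell most by the same rule. In all, 5227 genes differed, 2711 higher and 2516 lower in KO (7080 at an unadjusted p under 0.05), and at a fold of at least 1.5, 329 were higher and 542 lower.

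Keratinocyte differentiation genes rose in KO, 23 of 31 with 1 lower (24 and 2 when adjusted over the list alone, median 0.43, camera, adjusted p = 2.14e-07, and adjusted p = 0.463 with an estimated correlation; fry 0.000537). The envelope precursors Ivl (0.81 ± 0.13) and Hrnr (1.20 ± 0.20) and the calcium binder Calm4 (0.54 ± 0.09) rose, while the keratin Krt2 fell by 1.60 ± 0.23. Cholesterol synthesis rose in 19 of 24 genes with 0 lower (19 and 0; 0.39; 1.08e-07, and adjusted p = 0.463 with an estimated correlation), through Pmvk (0.54 ± 0.08), Dhcr7 (0.47 ± 0.07), Sc5d (0.53 ± 0.08) and Fdps (0.59 ± 0.11). S phase fell in 25 of 30 with 0 higher (0 and 27; -0.34; 3.27e-09, and adjusted p = 0.463 with an estimated correlation), among them Usp1 (-0.27 ± 0.04), Prim1 (-0.35 ± 0.06) and Pold3 (-0.28 ± 0.05). DNA repair fell in 11 of 26 (12; 0.0156, and adjusted p = 0.463 with an estimated correlation), with Brca2 (-0.42 ± 0.12), Atr (-0.22 ± 0.05) and Atm (-0.22 ± 0.06). Fatty acid oxidation rose in 8 of 16 with 2 lower (8 and 2; 0.0167, and adjusted p = 0.651 with an estimated correlation), through Acadl (0.45 ± 0.05), Hadhb (0.25 ± 0.05) and Hadha (0.23 ± 0.04). Of 19 core clock genes 5 were higher and 10 lower (0.00279, and adjusted p = 0.463 with an estimated correlation). E-box outputs had 1 and 9 of 15 (5.25e-09, and adjusted p = 0.0677 with an estimated correlation) and ROR element genes 4 and 1 of 5 (5.91e-05, and adjusted p = 0.0677 with an estimated correlation). No camera call in any comparison held with an estimated correlation.

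Several metabolic and stress lists had changed members but no shift as a whole by camera in KO against WT. Among them were mitosis (Ttk 0.98 ± 0.10, Gtse1 -0.31 ± 0.10, camera, adjusted p = 0.403) and glycolysis (2 higher, 3 lower of 21, Pfkfb3 -0.77 ± 0.12, Pgk1 -0.27 ± 0.07, Gapdh -0.31 ± 0.08; 0.652). Others were NAD metabolism (Nmnat2 -0.91 ± 0.14, Parp1 -0.12 ± 0.03, Nampt -0.14 ± 0.05; 0.165, but lower by fry, adjusted p = 4.06e-04) and antioxidant response (5 higher, 3 lower of 22; Prdx6 -0.44 ± 0.05, Sod2 -0.33 ± 0.05, Gsta3 -0.91 ± 0.15, Nqo1 0.49 ± 0.08; 0.856). Nampt had adjusted p = 0.0566 without replicate 4 of WT at time point 4. Lipid enzymes moved both ways (8 higher, 4 lower of 21; Degs1 0.31 ± 0.05, Acacb -0.63 ± 0.10, Elovl5 -0.54 ± 0.09; 0.0948), as did glucocorticoid targets (1 and 3 of 15, Fkbp5 -0.85 ± 0.25; 0.403). So did interferon response (3 and 2 of 25; Ddx58 0.78 ± 0.07, Bst2 -0.45 ± 0.12; 0.856) and inflammation (4 and 2 of 24; Il33 0.68 ± 0.12, Ccl2 0.76 ± 0.15, Ccl20 1.42 ± 0.38, Krt6b -0.62 ± 0.14; 0.627). Oxidative phosphorylation had 2 higher of 34 (0.262), and 7 without replicate 3 of WT at time point 3. The basal layer had 1 higher and 3 lower of 14 (Dst -0.36 ± 0.11, Itga6 -0.29 ± 0.10, Sox6 -0.23 ± 0.08; 0.627). Sox6 had adjusted p = 0.0567 without replicate 3 of WT at time point 1, and 8 basal genes were called without replicate 4 of KO at time point 6. Heat shock had 3 higher and 1 lower of 17 (Hspa1b 0.34 ± 0.07; 0.627), and Hspb1 had adjusted p = 0.110 without replicate 4 of KO at time point 6. Immediate early genes had Socs3 lower (-0.47 ± 0.15) of 22, with a median of -0.02, a mean of -0.01 and an upward camera test (0.996).

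Markers of other cells differed as well between KO and WT. The follicle keratins Krt25 (-2.65 ± 0.53) and Krt71 (-2.95 ± 0.63) fell while the follicle regulators Msx2 (0.41 ± 0.07) and Trps1 (0.77 ± 0.14) rose (3 higher, 10 lower of 22, camera, adjusted p = 0.214). Melanocyte genes fell in 5 of 8 cases (Kit -0.73 ± 0.21, Tyrp1 -1.01 ± 0.32; 0.0259, and adjusted p = 0.651 with an estimated correlation). Tyr had adjusted p = 0.0721 without replicate 2 of WT at time point 4, which left 3 calls. T cell genes fell in 5 of 15 cases with Thy1 higher (0.76 ± 0.15; Cd2 -0.56 ± 0.13, Xcl1 -0.53 ± 0.15; 0.0152, and adjusted p = 0.876 with an estimated correlation), and 9 were called without replicate 4 of KO at time point 1. Of 14 Langerhans genes Epcam (-0.20 ± 0.06) and Fcer1g (-0.35 ± 0.11) fell (0.0352, and adjusted p = 0.891 with an estimated correlation; fry 0.0954). Sebaceous genes fell in 5 of 12 cases (Scd3 -0.64 ± 0.18; 0.0547), with 1 call without replicate 4 of WT at time point 4, where adjusted p was 0.0548 for Far2, 0.105 for Fa2h and 0.106 for Awat1. Globins rose in 3 of 5 erythrocyte genes (Hba-a1 0.98 ± 0.20, Hba-a2 1.03 ± 0.22; 0.00429, and adjusted p = 0.463 with an estimated correlation). Hbb-bs was lost (adjusted p = 0.172) without replicate 4 of KO at time point 6 and 5 were called without replicate 4 of WT at time point 6. Endothelial Flt1 (-0.61 ± 0.22) and Eng (-0.48 ± 0.17), fat cell Lpl (-0.95 ± 0.24), muscle Tnni2 (0.69 ± 0.15) and Ttn (-0.40 ± 0.10) and fibroblast Col6a1 (0.49 ± 0.13) changed in lists without a shift (0.612, 0.627, 0.669 and 0.846). Of 3 Merkel cell genes edgeR called 0 (0 at an unadjusted p under 0.05, camera 0.856).

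**Figure D4:**
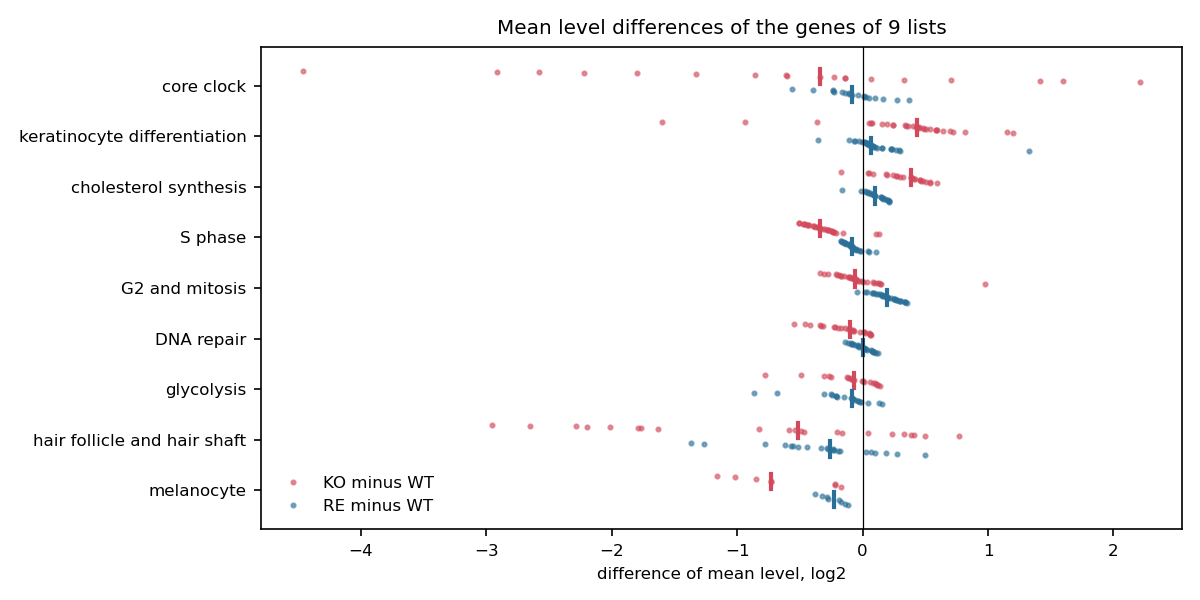
Log2 differences of mean level of the members of 9 gene lists, KO against WT (red) and RE against WT (blue); each point is 1 gene and the vertical bar is the median. Cholesterol synthesis had a median of 0.39 in KO and 0.10 in RE.

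RE epidermis lay close to WT in mean log2 level. Arntl was higher by 0.37 ± 0.06 (adjusted p = 9.31e-05) and Bhlhe41 lower by 0.57 ± 0.15 (0.0168), the 2 calls among 19 core clock genes. As CPM, Arntl averaged 61 in RE and 54.1 in WT. It lay below WT at time points 1 (64.1 against 96.1) and 6 (64.3 against 83.6) and above WT at the other time points. The serpins Serpinb13 (1.00 ± 0.19; 2.54e-04) and Serpinb3b (0.76 ± 0.14), Fcgr3 (0.92 ± 0.14), Kazald1 (0.65 ± 0.10; 5.24e-06), Nsg1 (0.62 ± 0.10) and Steap4 (0.61 ± 0.16) rose. Nav3 (0.73 ± 0.22) had adjusted p = 0.0927 without replicate 4 of RE at time point 3, and Lrrc32 (0.69 ± 0.20) had 0.0571 without replicate 4 of WT at time point 4. The muscle protein Pgm5 (-1.24 ± 0.19; 1.55e-05), the vesicle protein Syt1 (-0.89 ± 0.17), and the natriuretic receptor Npr3 (-0.82 ± 0.19) fell. So did the peptide Edn2 (-0.78 ± 0.20), the keratin Krt4 (-0.70 ± 0.16), the microRNA gene Gm26384 (-1.09 ± 0.09) and the pseudogene Gm13339 (-0.90 ± 0.13). Glycolysis fell in 5 of 21 genes with 1 higher (7 and 1 when adjusted over the list alone, median -0.09, camera, adjusted p = 2.94e-04, and adjusted p = 0.918 with an estimated correlation). Lower were Pfkfb3 (-0.68 ± 0.12), the lactate carrier Slc16a3 (-0.87 ± 0.20), Pgk1 (-0.31 ± 0.07) and Pfkl (-0.24 ± 0.06). In all, 748 genes differed from WT, 384 higher and 364 lower (3176 at an unadjusted p under 0.05); with RLE factors 305 were higher and 423 lower, and with DESeq2 374 and 517.

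Single members of further lists moved between RE and WT. The RNA sensor Ddx58 (0.24 ± 0.07) had adjusted p = 0.0831 without replicate 4 of RE at time point 4, where Il33 (0.39 ± 0.12) had 0.0812, and G6pdx (0.16 ± 0.05) had 0.0907 without replicate 4 at time point 6. Ccl20 (1.34 ± 0.39) had 0.456 and the cystine carrier Slc7a11 (1.32 ± 0.37) 0.590 without replicate 1 of RE at time point 5. Epcam (-0.26 ± 0.06) and Msx2 (0.27 ± 0.07) kept their calls. Camera with the preset correlation put ROR element genes (adjusted p = 0.0304), mitosis (2.94e-04, median 0.20), cholesterol synthesis (0.0112) and erythrocyte genes (0.00938; 4 called without replicate 4 of WT at time point 6) up. It put S phase (0.00138, median -0.08), immediate early (0.0055), heat shock (0.0158) and melanocyte genes (0.0495) down, and each of these 8 had adjusted p = 0.918 with an estimated correlation. fry called 0 lists, the smallest adjusted p being 0.192. In 22 lists 0 of 368 genes were called in edgeR (50 at an unadjusted p under 0.05, DESeq2 called 4 and voom 38). Inflammation had a median of 0.21 and a mean of 0.33 with a downward camera test (0.935), fibroblast markers 0.04 and 0.13 with a downward test (0.585), and fat cell markers 0.01 and -0.04 with an upward test (0.527).

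Against KO, RE moved the mean log2 level of most core clock genes back toward that of WT. Averaged as CPM over 24 animals, RE stayed below WT for Dbp (28.7 against 55.2), Ciart (8.13 against 14.6) and Per2 (36 against 63.4). For Per2 the KO average was 36.3, so RE did not move it toward WT. Also below WT were Nr1d1 (109 against 161), Nr1d2 (139 against 176), Bhlhe40 (244 against 329) and Bhlhe41 (1.97 against 3.5). Arntl (61 against 54.1) and Clock (113 against 106) lay above WT. Tef (287 against 336) and Hlf (164 against 166) lay closer to WT. The differences that follow are on the log2 scale. Nr1d1 rose by 4.30 ± 0.18, Nr1d2 by 2.78 ± 0.11, Dbp by 2.36 ± 0.22, Per3 by 2.27 ± 0.14 and Ciart by 1.56 ± 0.15. Arntl rose by 0.98 ± 0.06, Tef by 0.88 ± 0.10, Bhlhe41 by 0.77 ± 0.16 and Hlf by 0.36 ± 0.08. Npas2 fell by 1.94 ± 0.13, Cry1 by 1.63 ± 0.10, Nfil3 by 0.82 ± 0.19 and Clock by 0.23 ± 0.04. The secreted protein Crispld2 (2.44 ± 0.25), Arsi (2.23 ± 0.16) and the pseudogenes Ifi203-ps (2.88 ± 0.18) and Gm9989 (2.77 ± 0.18) rose. H19 (-2.25 ± 0.23), Igf2bp2 (-1.90 ± 0.14), Ttc9 (-1.53 ± 0.07), F3 (-1.51 ± 0.18) and Abhd12b (-1.47 ± 0.10) fell. In all, 4174 genes differed, 2137 higher and 2037 lower in RE (6394 at an unadjusted p under 0.05). With RLE factors 2015 were higher and 2155 lower, with DESeq2 2151 and 2259, and at a fold of at least 1.5, 372 and 236. To keep selection and reading in separate animals, genes were selected on KO against WT in replicates 1 and 2 and read in replicates 3 and 4. There 2908 genes had a median shift of 0.29 for KO and 0.05 for RE (18.1% left). With the replicates exchanged 1615 genes had 0.36 and 0.10 (28.2%). Both shifts were read against the same WT animals, so they are not independent of each other.

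Several epidermal programs changed in RE against KO. Differentiation fell in 21 of 31 genes with 3 higher (22 and 3 when adjusted over the list alone, median -0.35, camera, adjusted p = 3.63e-06, and adjusted p = 0.571 with an estimated correlation). Members included Ivl (-0.78 ± 0.13), Sprr1a (-0.83 ± 0.18) and Abca12 (-0.37 ± 0.08), with Krt2 (1.83 ± 0.23) higher. Cholesterol synthesis fell in 10 of 24 (12; -0.23; 4.18e-05, and adjusted p = 0.797 with an estimated correlation; Pmvk -0.38 ± 0.08, Sqle -0.40 ± 0.11). S phase rose in 11 of 30 (21; 0.26; 1.15e-05, and adjusted p = 0.797 with an estimated correlation; Prim1 0.27 ± 0.06, Tyms 0.34 ± 0.09). Mitosis rose as a list (3 higher, 1 lower of 32; 2.52e-04, and adjusted p = 0.832 with an estimated correlation; fry 0.114) with Ttk lower (-0.80 ± 0.10). Without replicate 3 of KO at time point 6 it had 10 calls. DNA repair rose in 9 of 26 with 1 lower (15 and 1; 0.00751, and adjusted p = 0.571 with an estimated correlation; Mutyh 0.32 ± 0.07, Fancd2 0.44 ± 0.10). NAD metabolism rose in 3 of 11 (6; 0.0221, and adjusted p = 0.158 with an estimated correlation; Nmnat2 0.91 ± 0.14). Heat shock fell in 4 of 17 (0.0221, and adjusted p = 0.797 with an estimated correlation; Hspa1b -0.44 ± 0.07). T cell genes rose in 4 of 15 with Thy1 lower (0.00565, and adjusted p = 0.822 with an estimated correlation). They had 2 calls without replicate 1 of RE at time point 3 and 10 without replicate 4 of KO at time point 1. Of the core clock genes 9 were higher and 5 lower (0.00235, and adjusted p = 0.359 with an estimated correlation). E-box outputs (8 and 1; 3.8e-08, and adjusted p = 0.123 with an estimated correlation) and ROR element genes (1 and 4; 2.58e-04, and adjusted p = 0.123 with an estimated correlation) moved apart in the other direction.

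Other lists had changed members in RE against KO without a shift by camera. Antioxidant response had 5 higher and 4 lower of 22 (Prdx6 0.42 ± 0.05, Gsta3 1.09 ± 0.15, Nqo1 -0.53 ± 0.08, median -0.01, mean 0.11, upward camera test, adjusted p = 0.827), and glycolysis 1 and 5 of 21 (Pgam1 -0.23 ± 0.05; 0.0706). Lipid and ceramide synthesis had 4 and 8 of 21 (Acacb 0.61 ± 0.10, median -0.11, mean 0.01, downward test; 0.236) and fatty acid oxidation 1 and 4 of 16 (Acadl -0.44 ± 0.05; 0.0824). Inflammation had 3 higher and 4 lower of 24 (median 0.04, mean 0.23, downward test; 0.463), with Ccl2 (-0.78 ± 0.15), Ptgs2 (-0.70 ± 0.23), and S100a8 (2.84 ± 0.64). S100a9 (2.47 ± 0.60) had adjusted p = 0.0532 without replicate 1 of RE at time point 5. Interferon response had 4 and 2 of 25 (Ddx58 -0.54 ± 0.07; 0.647), and glucocorticoid targets 2 and 1 of 15 (0.455), where Fkbp5 had adjusted p = 0.113 without replicate 1 of RE at time point 5. The basal layer (0.964) had 6 calls without replicate 4 of KO at time point 6. Immediate early Egr2 (-0.31 ± 0.11; 0.0586), fibroblast Fn1 (-0.70 ± 0.14, median 0.25, mean 0.06, downward test; 0.514), endothelial Eng (0.56 ± 0.17; 0.534) and follicle Shh (2.09 ± 0.57) and Trps1 (-0.70 ± 0.14; 3 higher, 4 lower of 22; 0.766) changed. So did muscle Tnni2 (-0.49 ± 0.15; 0.942), fat cell Lipe (0.26 ± 0.07; 0.276, but higher by fry, adjusted p = 0.0283), sebaceous Awat1 (0.75 ± 0.28; 0.223) and Hba-a1 (-0.56 ± 0.20; 0.189). Awat1 had adjusted p = 0.102 without replicate 3 of RE at time point 4, with 4 sebaceous calls without replicate 3 of KO at time point 5, and Hba-a1 0.180 without replicate 4 of KO at time point 6. Oxidative phosphorylation, Langerhans, melanocyte and Merkel cell lists had 0 of 59 genes in edgeR (3 at an unadjusted p under 0.05, DESeq2 called 1 and voom 3).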

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

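The tests of the 12 h component within KO and within RE, the tests of pseudogenes and the bootstrap interval were chosen only after the result was seen.

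By a test of gaps, 4 libraries stood apart from the other 3 of their group in 1 measure. Replicate 1 of RE at time point 6 had 5.94% mitochondrial reads against 2.53 to 2.78%. The 10 most abundant genes took 12.4% of reads in replicate 4 of KO at time point 6 against 7.53 to 7.96%, and 7.10% in replicate 2 of RE at time point 2 against 7.45 to 7.49%. Arntl had 30.4 CPM in replicate 1 of KO at time point 3 against 31.5 to 31.7 CPM. These were 4 of 90 combinations of a group and 1 of 5 measures, and chance gives 4.5. That count does not make each flagged library ordinary. Replicate 4 of KO at time point 6 also lay at -96 on the first principal component. The other KO animals of that time point lay at -31.6 to -7.9. Its chi-square per gene against them was 213 to 288, and among them it was 23.7 to 66.4. Replicate 4 of WT at time point 6 was not flagged here, although it stood apart from its group as described below.

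The rhythm of clock genes differed between KO and WT by a test of the difference itself. The curve of the difference swung by 4.75 log2 units for Dbp, 4.00 for Per2, 3.39 for Ciart, 3.11 for Nr1d1, 3.08 for Per3, 3.04 for Npas2, 2.74 for Bhlhe41, 2.73 for Tef, 2.27 for Arntl, 1.95 for Cry1, 1.94 for Nr1d2, 1.13 for Cry2, 0.90 for Hlf and 0.59 for Clock. Hlf had adjusted p = 0.0738 without replicate 1 of KO at time point 6. Outside the clock it swung by 1.97 for Ttc9, 1.5 for Pdxk, 1.38 for Rps27rt, 1.22 for Rps15a-ps4, 1.15 for Leo1, 1.01 for Cx3cl1, 1.00 for Fam234b and 0.84 for Zhx2. The real assignment of animals called 1150 genes for a different rhythm, and among 75 assignments within time points, the real one included, 2 called as many, the highest other with 1598. What made that assignment call more genes than the real one was not tested.

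RE and WT also differed by that test, with 402 genes against at most 7 in the other 74 assignments. Only the real one of 75 called as many, which is the smallest share they can give. The curve of the difference swung by 4.17 for Dbp, 3.27 for Ciart, 3.00 for Per2, 2.79 for Nr1d1, 2.74 for Per3, 2.62 for Npas2, 2.52 for Bhlhe41, 2.31 for Tef, 2.05 for Arntl, 2.00 for Nr1d2, 1.61 for Cry1, 1.06 for Cry2 and 0.55 for Clock. Outside the clock it swung by 1.93 for Ttc9, 1.27 for Inpp1 and for Rps27rt, 1.11 for Gm11663, 1.06 for Rpl31-ps14, 1.04 for Rps15a-ps4, 1.02 for Leo1 and 0.89 for Fam234b.

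Random assignments of animals to time points within a genotype called at most 375 genes in WT, 23 in KO and 36 in RE against 2031, 1088 and 501 for the real times (1 of 75 as large in each, the real one). For mean levels the highest other assignment called 595 genes for KO against WT (real 5227), 7 for RE against WT (real 748) and 679 for RE against KO (real 4174), again 1 of 75. No other assignment reached these 6 counts, and 1 of 75 is the smallest share they can give. The assignments to time points move single animals. They therefore leave open differences between harvests that all animals of a time point share. For a different rhythm of RE and KO the real value was 0 in edgeR (364 genes at an unadjusted p under 0.05; 0 in DESeq2 and voom) and the highest other 2. All 75 assignments must call at least 0 genes, so this comparison decides nothing.

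The 24 h calls of KO, in animals with 0 of 19 core clock genes called rhythmic, overlapped with those of RE in 305 genes with the same phase. Reads shared with pseudogenes argue little for KO, where 9.4% of calls were pseudogenes against 8.6% of the genes tested, but RE had 15.4%. Step-like differences between time points stay open in both. In KO a 12 h component called 0 genes in edgeR against 1088 at 24 h, but at an unadjusted p under 0.05 it had 2971 against 4690 in a model of all harmonics (not run in other tools). The KO calls also fell to 202 without time point 2 and to 17 by the rank test. In RE the 12 h component called 133 against 501, a ratio of 0.265, and 496 against 692 in the model of all harmonics. The form of this test stated in advance, for KO and RE together, met neither of its bounds. A time course of harvest or handling shared by all genotypes may contribute. The 24 h terms of KO genes correlated with those of WT at 0.303 (bootstrap interval 0.173 to 0.423, across the bound of 0.3 set in advance). The bootstrap drew genes and not animals, so its interval leaves out the spread between animals. The terms of RE genes correlated with WT at 0.514. KO and RE terms correlated with each other at 0.735 for KO genes and 0.822 for RE genes. WT shared less with KO: 362 of the 1088 KO genes (33.3%) had a rhythm called different from WT, and 106 were called in both (119 expected). For KO such a time course cannot be told apart from cycles driven by the environment, since no label gives the harvest order.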

How the results depend on the processing

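The tests without single libraries, time points or the lowest libraries on the first principal component, and the 24 h terms within time point means, were chosen only after the result was seen. Among 483 values of single genes, 6197 alternatives kept the side of the threshold, 758 lost it and 17 gained it, and a called difference of mean level changed sign in 0 of them. The balance of higher and lower calls was less firm. For KO against WT (2711 higher, 2516 lower) it turned without a filter (2310 and 2589), with only the genotypes concerned (2513 and 2577), at a fold of at least 1.5 (329 and 542), without replicate number 2, 3 or 4 (2034 and 2044, 2105 and 2126, 2208 and 2308) and without the lowest libraries on the first component (2705 and 2743). For RE against WT (384 and 364) it turned with RLE factors (305 and 423), without a filter (193 and 293), with DESeq2 (374 and 517), with only the genotypes concerned (386 and 522), at a fold of at least 1.5 (42 and 57), without the lowest libraries (579 and 611) and without each replicate number. For RE against KO (2137 and 2037) it turned with RLE factors (2015 and 2155), with DESeq2 (2151 and 2259) and without each replicate number, and was 372 and 236 at a fold of at least 1.5. The cause was not tested.

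With limma voom, rhythmic genes numbered 4913 in WT, 2575 in KO and 2034 in RE, different rhythms 3193 for KO against WT and 2645 for RE against WT, and different mean levels 2219 for RE against WT. DESeq2 gave 696 different rhythms for RE against WT. With only the genotypes concerned, KO had 399 and RE 176 rhythmic genes, while WT had 2514. With time point as a factor RE had 1112, and different rhythms were 574 for KO against WT and 192 for RE against WT. The rank test called 17 genes in KO and 0 in RE (3006 in edgeR at an unadjusted p under 0.05; 726 called by DESeq2). Without a filter 486 genes differed in mean level between RE and WT. A fold of at least 1.5 left 873, 377 and 169 rhythmic genes in WT, KO and RE and 871, 99 and 608 mean level differences for KO against WT, RE against WT and RE against KO. The cause was not tested for any of these.

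Without time point 1, 2, 3, 5 or 6 WT had 1019, 1246, 1330, 1224 or 3261 rhythmic genes; without time point 2, 3, 5 or 6 KO had 202, 1924, 554 or 681; without time point 2 or 5 RE had 179 or 246. Without the lowest library of each genotype on the first component 1190 genes differed in mean level between RE and WT. Without replicate 2 of KO at time point 5 KO had 645; RE had 302 without replicate 4 of time point 5 and 880 without replicate 2 of time point 6. Leaving out each replicate number gave 945 to 1416 rhythmic genes in WT, 202 to 737 in KO and 73 to 675 in RE. Leaving out each single library gave at most 2460 in WT, 1527 in KO, 1622 and 573 different rhythms for KO and RE against WT, and 5642, 1021 and 4549 different mean levels for KO against WT, RE against WT and RE against KO. Leaving out each replicate number gave 171 to 934 different rhythms for KO against WT, 58 to 276 for RE against WT and 0 to 0 for RE against KO, and 3420 to 4516, 273 to 390 and 2500 to 3201 different mean levels in the same order.

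With the replicate number as a block, rhythmic genes were 1885, 1005 and 427, different rhythms 1038, 370 and 0 and different mean levels 5132, 681 and 4066, all within 1.5 times. The numbers showed at most weak pairing of animals on average. Libraries of the same number correlated at 0.07, 0.07 and 0.04 on average for KO with WT, RE with WT and RE with KO. Those of different numbers gave -0.02, -0.02 and -0.01. Single pairs of the same number ran from -0.28 to 0.68, -0.49 to 0.34 and -0.42 to 0.43. Of 24 libraries 7, 10 and 7 correlated best with their own number. The block is common to all time points, so pairs within a single time point stay open. Scaling moved the median of all genes by less than 0.1. No setting varied depth, so what depth limits was not tested. At the real library sizes and spread between animals 58.2% of 1.5-fold swings were called in simulated WT data.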

Other observations

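The placement of each animal on the WT clock cycle, the tests of the axis of RE clocks, of the 4 largest RE clocks and of clocks in step with harvest, the positions between genotypes, the keratin values and the 4 genes high in 1 RE animal were chosen only after the result was seen.

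Single RE animals carried clock gene states of WT size. Scored on all 19 core clock genes against the fitted WT rhythms (size 1 = WT fit), WT animals had a median clock size of 1.10, KO animals 0.15 (0.05 to 0.35) and RE animals 0.27 (0.03 to 1.13). The largest RE clocks were replicate 4 of time point 2 (1.13; clock at 5.5 h, harvest at 4 h), replicate 3 of time point 4 (1.09; 14.7 h, 12 h), replicate 1 of time point 6 (0.87; 20.9 h, 20 h) and replicate 2 of time point 1 (0.68; 1.7 h, 0 h). Replicate 3 of time point 4 held 133 CPM of Per2 against 58.2 in the next RE animal, and replicate 4 of time point 2 held 304 CPM of Nr1d1 against 171. In 12 of 24 RE animals the clock lay within 3 h of the harvest time, against 23 in WT, 7 in KO and 6 by chance. The clocks were in step with harvest with a mean size of 0.203 in RE (permutation p = 0.00086) and 0.029 in KO (permutation p = 0.159).

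Replicate 1 of RE at time point 5 stood out in 4 genes. It held 97.5 CPM of S100a8 against at most 2.22 in the other RE animals, 149 against 3.33 CPM of S100a9, 23.1 against 1.33 CPM of Lcn2 and 9.33 against 0.462 CPM of Sprr2d.

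The nearly absent shared rhythm of RE may come from running clocks that differ between animals in phase, in size or in both. Their phases were not scattered at random. In 12 of 24 RE animals the clock lay within 3 h of harvest, against 6 by chance. The mean size in step with harvest was 0.203 (permutation p = 0.00086). After time point means were removed, correlations among the 19 clock genes over RE animals followed those of the WT peak times (Spearman 0.636, 95th percentile of permutations 0.132, permutation p = 1e-04, the smallest they can give), and those over KO animals did not (0.001, permutation p = 0.475). WT animals, which were in step, gave 0.604, so this test shows clock states that differ within time points and not how far phases scatter. A few large clocks as the only source are argued against by 0.454 without the 4 largest (95th percentile 0.136). A single axis of strength stays open: the narrow axis of RE clock positions had a variance of 0.0598, above 0.0314 for the wide axis of KO but close to 0.0595 for the narrow axis of WT. In simulated animals, with the noise of each gene shuffled separately, the test found scattered clocks of 25% of WT size in 20 of 20 cases. It called absent clocks in 1 of 20. Shuffling each gene separately removes the correlation between genes, as the permutations do. That share therefore does not show how often correlated genes without a clock are called.

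Differences of mean level between RE and WT could come from alleles linked to Arntl rather than from missing clocks elsewhere. Of 158 genes within 10 Mb of Arntl 6 were called, and of 18379 elsewhere 741, a ratio of 0.942 (Fisher's exact test, p = 1). This argues against an excess of changed genes within 10 Mb of Arntl. A window of 158 genes could not hold most of the 748 differences, so the test cannot decide whether linkage is the main source. Longer linked segments were not examined. Unlinked strain differences and the absence of clocks outside the epidermis stay open, untested.

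Replicate 4 of WT at time point 6 stood apart from its group. On a scale of 50 genes from WT (0) to RE (1) it lay at 0.95 with the other 23 WT libraries at -0.26 to 0.52, and its clock size was 0.16. It had 8.36% mitochondrial reads against 2.73 to 5.70% in the other 3 animals, and 12.3% of reads in the 10 most abundant genes against 7.05 to 8.01%. Its keratins were Krt14 11.13 (others 11.95 to 12.61), Krt5 12.02 (12.85 to 13.36), Krt1 13.25 (11.83 to 12.17) and Krt10 14.41 (13.18 to 13.33) log2 CPM. Replicate 4 of KO at time point 6 had Krt14 9.37, Krt5 10.48, Krt1 13.41 and Krt10 15.07. Replicate 1 of RE at time point 6 lay at 0.72 on the scale, with the other RE libraries at 0.43 to 1.22.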
